A study of Nicotiana tabacum with 4 samples.

How the data were processed

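Leaf RNA of wild-type tobacco and of an ODC-RNAi line was measured on 4 single-colour Agilent tobacco gene expression arrays, 2 per group. Per the labels' protocols, RNA was extracted on RNeasy columns, and 500 ng of total RNA per sample was copied from an oligo-dT primer carrying a T7 promoter, so that the signal reports polyadenylated transcripts, and labelled with Cy3 during transcription. Groups were taken from the sample titles and replicate numbers from the same titles, whose letters before the number, TR, are not spelled out in the labels. They may stand for technical replicate, and the p-values would then say nothing of variation between plants.

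Per the file headers, the scans were read with Agilent Feature Extraction 11.5.1.1, which gave an intensity for each spot. The processed intensity in the deposited files is background-subtracted and detrended within the array, per the file headers, and is not normalized between arrays. The deposited flags mark spots well above background (a signal above the background by 13 times its standard deviation, per the file headers), saturated spots and outlier spots. The authors' deposited value table holds log2 values of the same arrays. It has 40424 rows, of which 37520 matched exactly 1 probe by identifier. Set against the scanner values it was the same quantity on the log2 scale and in the same direction (Pearson r of 0.9999999 across probes on every array), shifted by a further constant of -0.214 to -0.237, and its column medians were -3.534 and -3.527 in wild type and -3.674 and -3.688 in ODC-RNAi. How the authors made it is not given in the sources used here.

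For the main result, log2 of the processed intensity was taken, control spots and 13 to 20 outlier spots per array were left out, spots of a probe were averaged, and the 75th percentile of each array was subtracted. Of 43759 probes, the 29196 well above background on both arrays of at least 1 group were tested, and 14563 were not. Each was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with group as the only term and a two-sided test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 1.98. Where a probe was not well above background on any array of a group, an "at least" fold is given: the mean of the bright group against the mean, for the dim group, of the higher of the lowest well-above-background signal of the array and the probe's own signal. This applied to 843 probes, 339 dim in wild type and 504 dim in ODC-RNAi. Such a bound rests on group means and does not allow for the spread between arrays.

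Gene names are those of the array design, can be old, and often rest on partial similarity to proteins of other species. A description naming a protein was found for 5957 probes, and 16014 were marked unknown. None of the identifiers matched the reference gene table used here. A total of 2406 identifiers had several tested probes, and 37 of these had probes called in opposite directions. Before the data were examined, 36 gene lists were fixed as words in the description. In a list, the probe with the highest mean stood for each identifier, and the 32 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. The genes named were also fixed beforehand: every ODC probe and every member of the 2 polyamine lists past the threshold, the 12 largest rises and 12 largest falls with fully separated arrays and a protein name (1 per name), and the 2 largest rises and falls of each list. In ranking, a bound took the place of the fold, a detail the fixed rule did not state. Descriptions reading only "unidentified" or "expressed protein" were counted as naming no protein after they had been seen.

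The fit was tested on simulated data for the comparison of ODC-RNAi with wild type, over 29196 probes, with 50 of them changed at each of 4 sizes. Of these 50, 5 were recovered at a log2 change of 0.5, 41 at 1, 39 at -1 and 47 at 2, with 3 false calls among the unchanged probes. With so few probes changed, the adjustment was stricter than in the data, so these shares do not carry over to the real comparison. With 60% of probes changed by folds drawn from the observed ones, 2.13% of the 10680 calls were false. The data gave more calls, 18723, and the simulated errors followed the fitted model, so this share does not carry over either. A shift planted in the photosynthesis list was found by camera, with no other list called. Errors were drawn independently for each probe and array, so the simulation cannot show effects of shared pools or correlated genes.

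Alternatives fixed before the data were examined were quantile and median scaling, a normexp background correction (offset 50) with quantile normalization, no filter and a strict filter on dim probes, the authors' deposited value table, a variance trend, the replicate number as a block, leaving out each array, a threshold of 0.01, an ordinary test per probe, a test against a 1.5-fold change, camera with an estimated correlation, and fry. Scaling to 7 spike-in control probes and lists restricted to descriptions naming a protein were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.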

Results

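Leaf transcripts were compared between wild-type tobacco (Nicotiana tabacum, variety xanthi) and a transgenic line in which ornithine decarboxylase (ODC) was knocked down by RNA interference, called ODC-RNAi here. ODC makes putrescine, the diamine from which the larger polyamines spermidine and spermine are built. The series title names the question as the transcriptome response to lowered ODC and lower polyamine levels. Leaf 3 from the top was taken from plants kept at 25 °C with 16 h of light per day. Each group had 2 arrays, and all 4 arrays lay on 1 slide, with the ODC-RNAi samples at positions 1 and 2 and the wild-type samples at positions 3 and 4. Each array carried 43759 probes other than controls. In wild type, 29294 and 29442 probes were well above background, and in ODC-RNAi 29080 and 29064. The 75th percentile of the signal was 1039.9 and 944 on the wild-type arrays and 1294 and 1272 on the ODC-RNAi arrays. No spot was saturated. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate plants, so the p-values measure only the spread between these arrays, which may be technical. The arrays of a group were close: the median standard deviation between them was 0.0486 in wild type and 0.0405 in ODC-RNAi on the log2 scale (29170 probes). Between the 5 spots of a probe on the same array the median was 0.0836 (11 probes). These are not like for like: the probes differ, and standard deviations of 2 values have a lower median than those of 5.

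The RNAi target was lower on both ODC-RNAi arrays at all 3 of its probes. For the contig TA13801_4097 (probe A_95_P007446) the normalised log2 signal was -0.23 ± 0.017 (SD, n = 2) in wild type and -2.69 ± 0.047 in ODC-RNAi, a 5.48-fold lower level (log2 fold change -2.45, standard error 0.046, limma adjusted p = 9.4e-05). The first probe of the ODC mRNA Y10472 (A_95_P122017) was 4.69-fold lower (log2 fold change -2.23, standard error 0.042, limma adjusted p = 9.3e-05). The second Y10472 probe (A_95_P160357) was far dimmer, with processed signals of 65.7 and 54.5 in wild type and 15.4 and 16.2 in ODC-RNAi. Its log2 fold change was -2.30 (standard error 0.069, limma adjusted p = 0.00017), and with a normexp background correction it was -0.61, still past the threshold. No genomic position is given for any gene, because none of the array's identifiers matched the reference gene table used here.

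**Figure D1:**
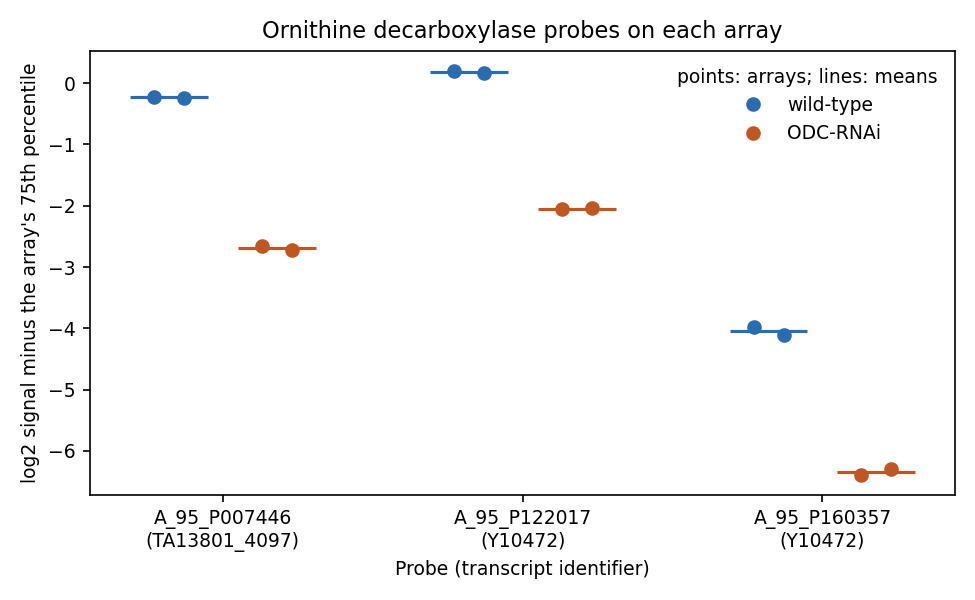
Normalised log2 signal (vertical axis, log2 signal minus the array's 75th percentile) of the 3 ornithine decarboxylase probes (horizontal axis) on each of the 4 arrays. Points are arrays and lines are group means. At each probe both ODC-RNAi arrays lie below both wild-type arrays, by 2.45, 2.23 and 2.30 on average.

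Transcripts of other enzymes of polyamine synthesis were mostly lower. Of 19 tested members, 12 were lower and 4 higher in ODC-RNAi (12 and 5 when adjusted over the list alone), with a median log2 fold change of -0.46, or -0.29 under median and -0.16 under spike-in scaling. As a set they did not pass camera, limma's competitive set test (adjusted p = 0.0747), although they did with quantile, median and spike-in scaling, with normexp correction, with a variance trend and with the authors' table. Arginine decarboxylase, which opens the second plant route to putrescine, was lower at all 5 identifiers that passed: AB110952 by -1.32, TA12478_4097 by -1.02, TA12480_4097 by -0.87, AF321137 by -0.84 and AF127239 by -0.76. Spermidine synthase was lower at TA15834_4097 (-0.76) and TA12763_4097 (-0.53). S-adenosylmethionine decarboxylase, which supplies the aminopropyl groups of spermidine and spermine, went both ways. U91924 (-1.32), TA11926_4097 (-1.30), DW002310 (-0.46), TA11924_4097 (-0.31) and TA14024_4097 (-0.18) were lower, and TA12251_4097 (0.52) and TA12252_4097 (0.22) were higher. The fall of TA11924_4097 shrank to -0.14 under median scaling and -0.00812 when arrays were scaled to spike-in controls, and that of TA14024_4097 to -0.00472 and, with the sign turned, 0.13, none of them past the threshold. Arginase 2 (TA14510_4097, 0.66) and spermine synthase (TA20570_4097, 0.25) were higher. Several of these identifiers are close copies of the same gene, and probes may not separate them.

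The list of polyamine breakdown and the linked synthesis of gamma-aminobutyrate rose. Of 7 members, 5 were higher and none lower (6 and 0 when adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.0457 with the preset correlation, and adjusted p = 0.498 with an estimated correlation). A copper-containing amine oxidase (TA19416_4097, matched over 31%), of the enzyme class that oxidises putrescine, was 3.21-fold higher (log2 fold change 1.68, standard error 0.069). An amine oxidase matched over 19% of its length (CV018352) was higher by 0.32. Glutamate decarboxylase, which makes gamma-aminobutyrate from glutamate and not from polyamines, gave the other 3: AF352732 (0.71), AF020424 (0.70) and U54774, which was not well above background in wild type and was at least 2.45-fold higher. The call was lost with the strict filter on dim probes (adjusted p = 0.129) and under median scaling (adjusted p = 0.133) and spike-in scaling (adjusted p = 0.185), and the median was 0.37 with normexp correction.

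Beyond the target, most measured transcripts differed between the lines, and the strongest falls and rises reached 10-fold and more. Of 29196 probes tested, 18723 (64.1%) passed an adjusted p of 0.05 in limma, 9050 higher and 9673 lower in ODC-RNAi. At least 2-fold changes were found for 3763 probes, of which 2447 (65.0%) were lower and 1316 higher. The arrays of the groups did not overlap at 24630 probes (84.4%). Chance would give 33.3% only if all arrays were independent samples, which the labels do not say. Directions are relative to the 75th percentile of each array: scaling to the median moved the median log2 fold change of all tested probes to 0.16, and scaling to spike-in controls moved it to 0.29. The share of higher probes among those called was 48.3%, and became 66.4% with median scaling and 76.1% with spike-in scaling. The excess of falls among 2-fold changes depended on it too: 1825 of 3750 were higher with median scaling and 2419 of 4015 with spike-in scaling. With normexp correction the 2-fold count was 1912.

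The named gene with the largest measured rise was a putative cinnamyl alcohol dehydrogenase (T114, AM851013), an enzyme class of lignin precursor synthesis, at 86.5-fold (log2 fold change 6.43, standard error 0.070, limma adjusted p = 7.4e-05). A gene annotated only as a transcription factor (TA15136_4097) was 41.5-fold higher (log2 fold change 5.37). A basic pathogenesis-related protein 1 (TA15468_4097) was at least 31.1-fold higher at 1 probe that was not well above background in wild type, and by 4.87 on the log2 scale at its brighter probe. Malate synthase (TA17732_4097), an enzyme of the glyoxylate cycle, was 23.3-fold higher, and a tonoplast intrinsic protein (TA13321_4097), a vacuolar aquaporin, 20.99-fold. Osmotin-like protein (TA12782_4097) was 16.9-fold higher, ferulate-5-hydroxylase (TA20437_4097) 15.6-fold, beta-galactosidase (EG649746) 14.95-fold and a pectin methylesterase inhibitor (TA14391_4097) 13.3-fold. An acyltransferase-like protein (acyl3a, AB176527) was at least 15.2-fold higher. The annotations of 2 further genes rest on 6% or less of a bacterial protein and say little of their function: TC162065 was at least 17.6-fold and EH621942, well above background on 1 of the 2 wild-type arrays, 13.9-fold higher.

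Among the falls, inositol-3-phosphate synthase (TA11819_4097), the first step of inositol synthesis, was 50.4-fold lower (log2 fold change -5.65, standard error 0.046, limma adjusted p = 6.7e-05). Galactinol synthase (TA17612_4097), which uses inositol to start the raffinose sugars, was lower by -4.31 and was well above background on 1 of the 2 ODC-RNAi arrays. The TAS14 dehydrin (TA15607_4097), a protein induced by abscisic acid and drought, was 17.2-fold lower, and extensin (X71602), a cell wall glycoprotein, 18.4-fold. Only bounds could be given for 4 other names, which were not well above background in ODC-RNAi. An aspartic protease-like protein (TA15706_4097) was at least 31.4-fold lower, a germin-like protein (DV999542) at least 17.3-fold, peroxidase PER9-6 (AY032674) at least 14.2-fold, and TA12476_4097, annotated from 7% of a bacterial haem o synthase, at least 64.5-fold. A leucine-rich repeat protein (LRR1, DQ358108) was 14.2-fold lower, geranylgeranyl diphosphate synthase 2 (GQ911584) 13.03-fold, and TA13358_4097, annotated from 6% of a bacterial efflux protein, 15.6-fold. A high affinity nitrate transporter (TA15912_4097) was lower by -4.25 with a standard error of 1.21 (limma adjusted p = 0.040). The ODC-RNAi arrays disagreed (SD 2.4) and only 1 of them was well above background. Its call was lost without the filter on dim probes (limma adjusted p = 0.101). With either wild-type array left out, the log2 fold change was -4.19 and -4.31. Over all 157 probes named by the rule, the median standard error was 0.063 and the second highest 0.453.

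Photosynthesis transcripts were lower almost throughout. Of 92 members, 78 were lower and 6 higher (78 and 8 when adjusted over the list alone), 37 of them at least 2-fold lower, with a median log2 fold change of -0.89. Camera gave an adjusted p of 5.5e-12 with the preset correlation and an adjusted p = 0.304 with an estimated correlation. The median was -0.58 under spike-in scaling. Chlorophyll a/b-binding proteins of the light-harvesting antenna had the largest falls among members measured in both groups, with CV017513 at -3.17 and TA12714_4097 at -2.53. The 2 largest rises were ferredoxins: ferredoxin III (TA16294_4097, 0.92) and a ferredoxin homolog (BP530244, 0.66). Chlorophyll synthesis moved with them. Of 21 members 18 were lower and none higher, at a median of -0.97, or -0.67 with members at their bound and -0.54 with normexp correction (camera adjusted p = 2.7e-05, and adjusted p = 0.406 with an estimated correlation). Geranylgeranyl reductase, which makes the phytol tail of chlorophyll, was lower at DV160212 (-1.99) and AJ007789 (-1.95). The 4 identifiers of plastid genes were too few to test. The Rubisco large chain (TA11967_4097) was lower by -0.33, a call lost under median and spike-in scaling, and ycf2 (BP528727) was higher by 0.37.

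Genes of protein breakdown rose. Of 174 members 92 were higher and 30 lower, with a median of 0.21, or 0.38 under median and 0.51 under spike-in scaling (camera adjusted p = 0.0017, and adjusted p = 0.339 with an estimated correlation). Vacuolar processing enzymes, proteases that mature vacuolar proteins, had the largest rises among members measured in both groups. TA13611_4097 (1b, matched over 11%) was at 3.58 and AB075947 (1a) at 2.88. A RING finger-like protein (EB441795, matched over 11%) fell by 3.46 on the log2 scale, and cysteine protease Cp5 (TA22114_4097) was at least 8.95-fold lower.

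**Figure D2:**
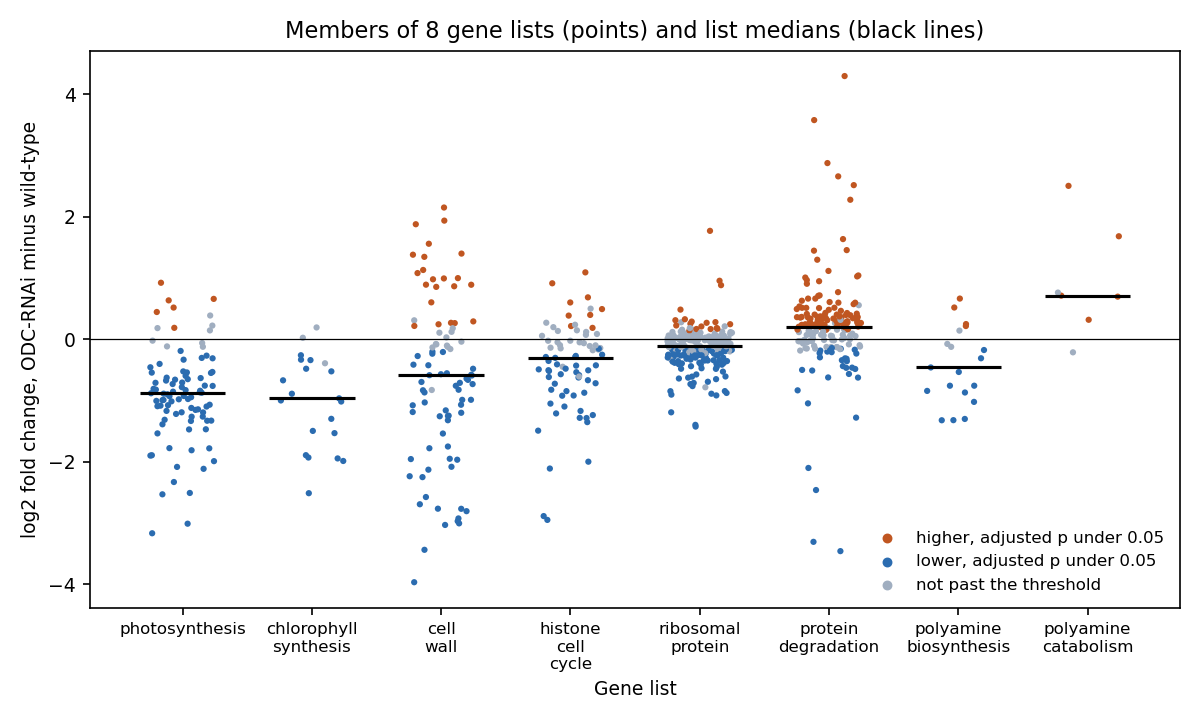
Log2 fold change (vertical axis, ODC-RNAi minus wild-type) of each tested member of 8 gene lists (horizontal axis). Points are transcripts, coloured by whether limma called them higher, lower or neither, and black lines are list medians. The medians of photosynthesis (-0.89) and chlorophyll synthesis (-0.97) lie lowest, and that of polyamine breakdown (0.71) highest.

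Cell wall genes were mostly lower, with 54 of 89 members lower, 22 higher and a median of -0.59, or -0.28 under spike-in scaling, -0.34 with normexp correction and -0.37 without the filter on dim probes (camera adjusted p = 0.0038, and adjusted p = 0.453 with an estimated correlation). Extensin X71602 (-3.97 at its brighter probe) and a polygalacturonase-inhibiting protein (BP530860, -3.44, matched over 22%) fell most. Another polygalacturonase-inhibiting protein (BP531572, 2.15) and the xyloglucan-modifying enzyme XTH5 (TA15154_4097, 1.94, matched over 17%) rose most. Histone, cyclin and tubulin genes were lower at 41 of 75 members and higher at 9, at a median of -0.30 (camera adjusted p = 0.0017, and adjusted p = 0.406 with an estimated correlation). Under median scaling this median was -0.13, with normexp correction -0.19 and under spike-in scaling -0.0012, so the fall of the typical member depends on the scaling, while the list stayed past the threshold in camera. Histone H2B (BP532655, -2.95, well above background on 1 of the 2 ODC-RNAi arrays) and a kinesin heavy chain (EB441102, -2.89, matched over 10%) fell most, while an A-type cyclin (D89636) was higher by 1.09. A cyclin A-like gene (X92964), not well above background in wild type, was higher by 0.91 (standard error 0.20), with a bound of 1.75-fold. The calls of both cyclins were lost without the filter on dim probes (limma adjusted p = 0.082 for D89636 and 0.060 for X92964). Lipid transfer and wax genes were lower at 7 of 10 members, at a median of -1.39 (camera adjusted p = 0.0358, and adjusted p = 0.498 with an estimated correlation). Lipid-transfer protein 2 (EG649620, -2.97, well above background on 1 of the 2 ODC-RNAi arrays) and TA12243_4097 (-1.95) led these falls, and 2 glycolipid transfer protein-like contigs were higher, TA13468_4097 by 0.48 and TC124289 by 0.19. Without the filter on dim probes the median of this list shrank to -0.13 over 21 members and the call was lost (adjusted p = 0.112). With the strict filter the median was -1.09 and the call was lost too (adjusted p = 0.0682), and with normexp correction the median was -0.90.

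Ribosomal protein genes shifted little. In this list 90 members were lower, 18 higher and 126 neither (79 lower and 16 higher when adjusted over the list alone), at a median of -0.11 (camera adjusted p = 0.014, and adjusted p = 0.339 with an estimated correlation), a direction that turned to 0.06 under median scaling and 0.19 under spike-in scaling. The call was lost under both (adjusted p = 0.616 and 0.903). Plastid-specific ribosomal protein 6 (TA18826_4097, -1.43) and TC123420 (-1.40, matched over 9%) fell most, and TA18496_4097 (1.77, matched over 11%) and 60S protein L8 (TA12096_4097, 0.96) rose most. In the lists not quoted with a count adjusted over the list alone, that count differed by at most 2 members in either direction.

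Jasmonate genes were lower at 14 of 21 members and higher at 3, at a median of -0.39, or -0.21 under median and -0.083 under spike-in scaling (camera adjusted p = 0.0358, and adjusted p = 0.498 with an estimated correlation). The MYB factor NtMYBJS1 (AB236951), named for its induction by methyl jasmonate, was at least 9.45-fold lower. Lipoxygenases, an enzyme class with members in jasmonate synthesis, went both ways, with EB430793 at -2.04, AJ344609 at 1.84 and BP533230 at 1.62. The descriptions do not say whether these members act in jasmonate synthesis. The 2 rising entries share an annotation, each matched over 16%, and may be copies of the same gene. The list's call was lost without the filter on dim probes (adjusted p = 0.0801) and with the strict one (adjusted p = 0.0631).

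**Figure D3:**
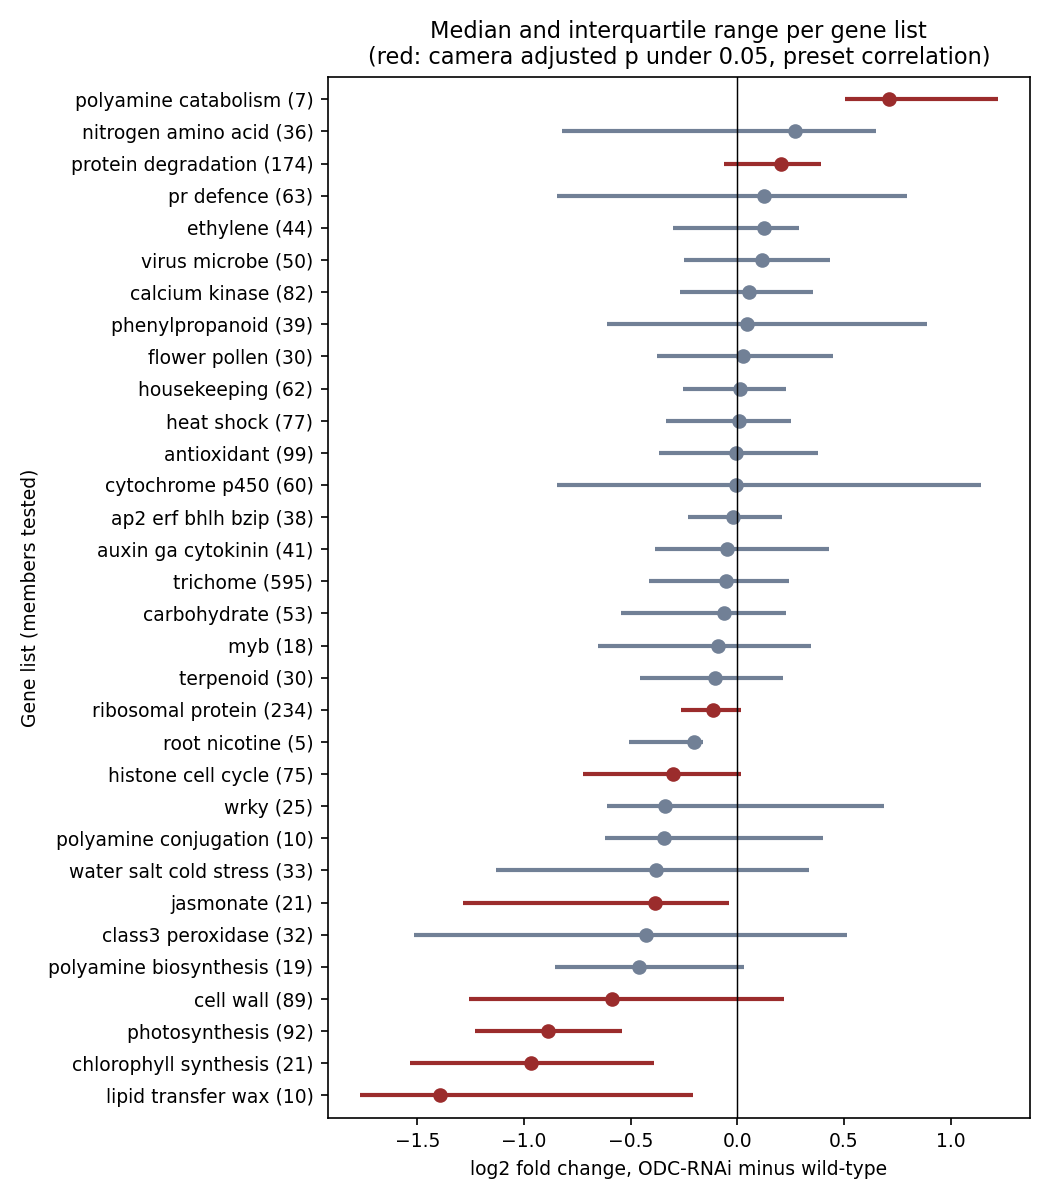
Median (points) and interquartile range (lines) of the log2 fold change (horizontal axis, ODC-RNAi minus wild-type) of the 32 gene lists tested (vertical axis, members tested in brackets). Red marks the 9 lists past an adjusted p of 0.05 in camera with the preset correlation, 2 of them upward and 7 downward.

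The other 23 lists tested did not pass camera, and most held large changes in both directions. Pathogenesis-related and defence genes were higher at 31 and lower at 22 of 63 members (camera adjusted p = 0.487). A thaumatin family protein (TA19075_4097, -3.34) and the PR-10 type protein NtMALD1b (AB518278, -2.96) fell most, against the rises of basic PR-1 and osmotin given above. Phenylpropanoid genes were higher at 18 and lower at 14 of 39 (adjusted p = 0.650), with the dehydrogenase T114 and ferulate-5-hydroxylase highest. A list of words for genes joining hydroxycinnamic acids to amines gave 3 higher and 6 lower of 10 (camera adjusted p = 0.487). A tyramine transferase (AJ005062) was higher by 1.17 and an anthranilate-type transferase (TA18150_4097) at least 7.41-fold. Agmatine coumaroyltransferase (TA22191_4097, -2.40) and a hydroxycinnamoyl transferase (TA21759_4097, -2.09) were lower. The description of TA21759_4097 names no amine, and it is also in the phenylpropanoid list. Its fall therefore says little of the joining to amines. Terpenoid genes were higher at 9 and lower at 12 of 30 (adjusted p = 0.585). Aristolochene synthase, which starts the tobacco phytoalexin capsidiol, was higher at EH619297 (3.68) and AF272244 (2.11), while vetispiradiene synthase (TA13185_4097, -2.62) was lower. Cytochrome P450 genes were higher at 25 and lower at 26 of 60 (adjusted p = 0.893), from the elicitor-induced CYP71D21 (AF368377, 3.40) to TA19537_4097 (-2.66) and EB432394 (-2.58). TA15860_4097 was at least 5.44-fold higher.

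Ethylene genes were higher at 16 and lower at 15 of 44 (camera adjusted p = 0.756). Its 2 largest falls were in ACC synthase, which makes the ethylene precursor (TC124167, -3.43, and AJ005002, -1.37), and its 2 largest rises in ACC oxidase, which turns it into ethylene (EB444740, 1.88, and AB012857, 1.77). Auxin, gibberellin and cytokinin genes were higher at 12 and lower at 16 of 41 (adjusted p = 0.915). Gibberellin 2-oxidase (EF471118, 2.92), which inactivates gibberellin, was higher, and gibberellin 20-oxidase (AB109762, -1.44), which makes it, was lower. The auxin-induced PCNT115 (BP192557) was higher by 1.79 and an Aux/IAA gene (EB438673) lower by -0.94. Water, salt and cold stress genes were higher at 11 and lower at 18 of 33 (adjusted p = 0.309, and adjusted p = 0.027 under spike-in scaling), with TAS14 and galactinol synthase lowest and the largest rises in DR752046, an aquaporin-like clone of a differential display that was at least 12.2-fold higher, and an LEA-like protein (EB439155, 1.37). Heat shock and chaperone genes were higher at 27 and lower at 25 of 77 (adjusted p = 0.767), from a DnaJ-like protein (TA14461_4097, 0.92) and a heat shock factor (TA15761_4097, 0.85) to an Hsp20 protein (BP130095, -1.02) and HSP101 (AF083343, -1.66).

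Antioxidant genes were higher at 33 and lower at 40 of 99 (camera adjusted p = 0.958). Glutathione S-transferases parA (TA12089_4097, 3.56) and EH624291 (2.25) rose most, and chloroplast peroxiredoxin Q fell most (EB434425 and EB679956, both -2.86). Class III peroxidases were higher at 9 and lower at 20 of 32 (adjusted p = 0.135), and passed downward under median scaling (adjusted p = 0.010), normexp correction (adjusted p = 0.041) and spike-in scaling (adjusted p = 0.0014), with CV021518 (1.92) and EH622672 (1.89) up and EB681738 (-2.36) down. Nitrogen and amino acid genes were higher at 18 and lower at 15 of 36 (adjusted p = 0.680). An amino acid transporter-like clone (DR752049) was higher by 1.80 and nitrate reductase 2 (TA12768_4097) by 1.26, and a second nitrate transporter (EH623224) was lower by -3.37. Carbohydrate genes were higher at 17 and lower at 19 of 53 (adjusted p = 0.709), from hexokinases 4b (AY553218, 1.19) and 4a (AY553217, 1.08) to beta-amylase 1 (EH622293, -2.12) and sugar transporter 10 (EB425028, -3.45).

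Regulators split in the same way. WRKY factors were higher at 8 and lower at 13 of 25 (camera adjusted p = 0.680), with NtWRKY-6 (AB063573, 1.94) and NtWRKY1 (AB022693, 1.75) up and CV016080 (-1.48) and WRKY55 (TA15810_4097, -1.37) down. MYB factors were higher at 7 and lower at 7 of 18 (adjusted p = 0.804), including NtMYBGR1 (AB279612, 2.02, well above background on 1 of the 2 wild-type arrays), LBM4 (AB028652, 1.60) and TA16366_4097 (-1.30). The AP2, bHLH and bZIP list gave 11 higher and 12 lower of 38 (camera adjusted p = 0.804), with BZI-4 (AY045572, 1.66) and EH622906 (1.70, matched over 5%) up. ATHB-7 (EB434774, -1.86) and EH623414 (-1.25) were down. ATHB-7 is annotated as a homeobox-leucine zipper protein, of another family, and was caught by the words of the list. The single NAC gene tested (TA14572_4097) was lower by -1.15. Calcium and receptor kinase genes were higher at 35 and lower at 24 of 82 (adjusted p = 0.547). The lectin receptor kinase NtlecRK2 (AB265222, 2.81) and the channel CBP7 (AF079871, 2.55) were highest, and EG650123 (-2.46, matched over 17%) and EB680801 (-2.43) lowest. Of 4 genes of translation factor 5A, which carries a residue made from spermidine, 1 was higher (TA12536_4097, 0.41) and none lower, too few to test.

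Lists kept as a check on other tissues and on the arrays did not pass either. Housekeeping genes were higher at 23 and lower at 18 of 62, at a median of 0.011 (camera adjusted p = 0.833). This median was 0.18 under median and 0.31 under spike-in scaling. An actin-like protein (TA21673_4097, 1.12), a polyubiquitin (TA17738_4097, 1.03) and alpha-tubulins DW001649 (-1.28) and AJ421412 (-1.24) changed. The trichome list was higher at 171 and lower at 230 of 595 (adjusted p = 0.585), but only 2 of its members had a protein name, since the word came from the name of a cDNA library. Its extremes were FG637805 (-5.36), FG635710 (-4.47), FG635575 (2.37) and FG638481, at least 11.2-fold higher. Flower and pollen words gave 13 higher and 11 lower of 30 (adjusted p = 0.893), with a MADS-box protein (TA20807_4097) at 1.57, a pollen library clone (CN949722) at 1.26, a pollen coat-like protein (TC159868) at -3.33 and a stigma entry (AY341252) at -2.06. A list of words for nicotine genes, kept as a check on roots, gave 1 higher and 3 lower of 5 (camera adjusted p = 0.647). CYP82E8 (DQ350361) was at least 1.81-fold higher, CYP82E5v2 (EB445799) was at -1.07 and a quinolinate enzyme (EB433697) at -0.51. The CYP82E members are not enzymes of nicotine synthesis, so this list says little of root tissue. Virus and bacterium words gave 20 higher and 14 lower of 50 (adjusted p = 0.309), among them TA12368_4097 (1.88), EU580436 (-1.80) and TA12538_4097 (-1.31), the first and last annotated from 6% of a bacterial protein. Median, mean and test differed in sign for 9 of the lists, none of them past the threshold.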

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

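Scaling to spike-ins and the lists restricted to protein names were chosen after seeing the data. The 3 ODC probes stayed lower and past the threshold in every alternative that gave a value; the authors' table gave one for a single probe. The number of changed probes stayed within 1.5 times the main 18723 in every alternative that tested for any change, from 12850 (probes changed, adjusted p under 0.05, ordinary t per probe, Benjamini-Hochberg) to 21447 with spike-in scaling, and from 14505 to 16411 with an array left out, where the lone array is assumed to vary like the other group. The 2-fold count of 3763 fell to 1912 with normexp and quantile normalization, whose offset of 50 shrinks the folds of dim probes by construction, and lay between 3794 and 3811 with an array left out. The treat test against a 1.5-fold change (probes changed, adjusted p under 0.05 and at least 2-fold, treat against 1.5-fold) called 4605 probes, held against this count and not against 18723. With an array left out, 4 to 6 named genes lost their call each time, all among TA14024_4097, TA12252_4097, TA20570_4097, TA11924_4097, TC124289, D89636, X92964 and TA15912_4097. The number of lists past the threshold, 9 in the main test, was 0 with an estimated correlation, where only 2 residual degrees of freedom are left to judge a list and 3 lists had an unadjusted p under 0.05. It was 29 with the directional and 32 with the mixed test of fry, which do not compare a list with other genes, and 6 to 11 otherwise. Spike-in scaling turned the median of the ribosomal list to 0.19 and the value of S-adenosylmethionine decarboxylase TA14024_4097 to 0.13, since it adds a constant to every probe. Same-numbered arrays did not deviate together (correlation of deviations -0.033 over the only 2 pairs), and the replicate block gave 17016 changed probes and 9 lists. Signals near background limit what the dim probes show: without the filter 17639 of 43759 probes were called.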

Other observations

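The gene groups in this part and all tests except the cyclic loess normalization were chosen after the results had been seen. The camera p-values of these groups are therefore no independent support. In a group of carbonic anhydrase and photorespiration genes, 16 of 23 members were lower and 6 higher, at a median of -0.57, or -0.27 under spike-in scaling (camera adjusted p = 0.0072 over the groups of this part, and adjusted p = 0.186 with an estimated correlation). Carbonic anhydrase, which supplies carbon dioxide near Rubisco, was lower at 6 of its 7 identifiers, from -3.65 at TC122974 and -3.58 at TA12191_4097 to -0.73 at BP133019, and higher by 0.55 at TA15280_4097. Several of these identifiers share an annotation and may be copies of the same gene. Of the 16 photorespiration members 10 were lower and 5 higher: glycine dehydrogenase DW000972 (-1.33) and hydroxypyruvate reductase EB429611 (-0.84) fell most, and serine-glyoxylate aminotransferase TA12092_4097 (1.06) and glycolate oxidase EB452103 (0.75) rose most. Peroxisomal beta-oxidation and glyoxylate cycle genes went the other way, with 11 of 14 higher and none lower, at a median of 0.48, or 0.65 under median and 0.78 under spike-in scaling (camera adjusted p = 0.0036, and adjusted p = 0.186 with an estimated correlation). Isocitrate lyase, which stands beside malate synthase in the glyoxylate cycle, was higher by 1.46 at TA13482_4097 and by 0.83 at TA13483_4097, and a peroxisomal thiolase (AY748246) by 1.02. Plastid ribosomal proteins were lower at 18 and higher at 3 of 28, at a median of -0.46, or -0.29 under median and -0.15 under spike-in scaling (adjusted p = 0.0064, and adjusted p = 0.186 with an estimated correlation). Cytosolic ones were lower at 52 and higher at 6 of 123, at a median of -0.13 (adjusted p = 0.0072, and adjusted p = 0.186 with an estimated correlation), which spike-in scaling turned to 0.17 and median scaling to 0.040.

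Vacuolar aquaporins moved far apart. Of 7 tonoplast intrinsic protein identifiers 4 were higher and 2 lower (camera adjusted p = 0.176): beside TA13321_4097, EB041772 (4.08), TA13320_4097 (3.90) and TA12174_4097 (3.09) were higher, and TA12950_4097 (-2.48) and EB429007 (-1.89) were lower. The first 3 share an annotation and may be copies measured by cross-hybridising probes. The list median was 3.09, and 3.39 after spike-in scaling. Both plasma membrane aquaporins tested were lower (median -0.65, or -0.48 under median and -0.35 under spike-in scaling). Glycosyltransferases were higher at 11 and lower at 7 of 23 (adjusted p = 0.176), among them the salicylic acid glucosyltransferase AF190634 (1.94) and the salicylate-induced IS5a (U32644, 1.24). Of 4 germin-like genes 3 were lower. The senescence-specific cysteine protease CP1 (AY881011), a member of the protein_degradation list not well above background in wild type, was higher by at least 2.26 on the log2 scale. Transporters of the ABC and MATE families were higher at 4 and lower at 3 of 12 (adjusted p = 0.477), and autophagy genes higher at 4 and lower at 1 of 7 (adjusted p = 0.162). Mitochondrial respiration was higher at 24 and lower at 8 of 48 (adjusted p = 0.040, and adjusted p = 0.3595 with an estimated correlation), but several members were annotated from 10% or less of an animal protein.

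Most tested probes differed between the lines, which on 2 arrays per group calls for a look at technical causes. A difference in scale that depends on intensity was tested by cyclic loess normalization: 18560 probes were still called, 17603 of them among the main 18723, which argues against it. An effect of array position or hybridization was set against the 7 spike-in controls. Once their common shift was removed, they differed between the groups by at most 0.073. The median absolute difference over tested probes was 0.318. This argues against so large an effect on the spike-ins. Each was taken as a median over its spots, so these 7 probes cannot show local effects or effects particular to other probes. Position also follows the group, as does the slope of the line fitted to the spike-in signals. That slope was 0.965 and 0.967 on the wild-type arrays, and 1 and 1.01 on the ODC-RNAi arrays. An effect of position therefore stays open, and so does the sampling. If the arrays of a group share plants, growth tray or extraction, any difference between those pools is counted as a difference between the lines. No value here separates the pools from the RNAi.

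Photosynthesis genes were lower while protein breakdown genes were higher. The brightness of the photosynthesis probes does not account for it: of 10000 random lists matched on mean signal the 2.5 percentile of the medians was -0.12, against -0.89. A later stage of leaf senescence in ODC-RNAi is a candidate explanation: in a list of 35 senescence-linked genes, which shares 10 members with the fixed lists, 18 were higher and 9 lower, at a median of 0.24 (0.41 under median and 0.54 under spike-in scaling) and a mean of -0.061. Camera in limma gave an adjusted p of 0.0836, with no other list in the adjustment, which leaves it undecided; a member had been seen to fall when the list was written, CP1 was not in it, and the knock-down itself, a different leaf age and a different share of green cells are untested.

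The ODC-RNAi arrays were brighter than the wild-type arrays although the spike-in controls were nearly level. Relative to the spike-ins the 75th percentile was 0.302 higher on the log2 scale, against at most 0.059 between arrays of a group. This could come from more polyadenylated RNA per unit of total RNA in the ODC-RNAi samples. More labelled RNA put on those arrays could give it only if the spike-ins were added after labelling. The labels do not say at which step the spike-ins were added or how much labelled RNA was used, so these cannot be separated here, and it stays open whether transcripts near the 75th percentile changed in amount.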
